A study of Rattus norvegicus with 16 samples.

How the data were processed

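Total RNA of the proximal femur was measured on 16 Affymetrix rat expression arrays, 4 for each of the strains F344, LEW, COP and DA. Per the labels' protocols, whole femora were taken from 4-week-old animals, RNA was isolated from the proximal femur with a phenol reagent and a column kit, and biotin-labelled cRNA was made from 5 ug of total RNA. The deposited intensity values are 1 signal per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes, which name no version. The scaling target, detection calls and filters were not given in the sources used here. The values themselves show that each array had a 2% trimmed mean of about 1000, so the authors' signals were already scaled array by array, and no further normalization between arrays was seen. Scaling of this kind sets the level of each array but leaves its shape, and signals of dim probe sets carry more noise. The raw scanner images were not used here.

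The table held 31099 probe sets, of which 57 were controls and were left out of every test. Probe sets were named through the annotation table of the array platform. Of the 31042 others, 20826 had 1 gene symbol, 436 had several and 9780 had none, and none was named from a probe set with several. The gene identifiers of 20758 probe sets matched a RefSeq gene table of the assembly GRCr8, which changed 0 symbols and gave each gene's chromosome and neighbours. No build was given for the array, so no coordinates are printed.

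Signals below 1 were set to 1 (255 values) and log2 values were taken with no pseudocount. Probe sets with a mean log2 value under the 40th percentile, a signal of 174, were left out, which kept 18625. limma 3.58.1 in R 4.3.3 fitted 1 mean per strain to all 16 arrays, with empirical Bayes moderation that follows an intensity trend, and gave an F-test over the 4 strains and all 6 pairwise contrasts. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the kept probe sets, with a threshold of 0.05. The fit had 12 residual degrees of freedom. A gene was represented by its kept probe set with the highest mean, which gave 10548 genes, 606 of them on chromosome 4. Of the genes tested, 2786 had more than 1 kept probe set.

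Lists of genes (29, of marrow, bone, cartilage, muscle and vascular cells, of signalling pathways and of housekeeping groups) were fixed before the data were examined, as were the comparisons, the filter, the thresholds and the alternatives named as planned. They hold 857 genes, of which 714 had a named probe set and 626 passed the filter. The 28 lists with at least 5 kept members were tested with camera, which sets the genes of a list against all other genes, with the correlation between genes estimated from the data; a preset correlation of 0.01 and the fry test were alternatives. The remaining list, of sex-linked genes, was described only. The share of called genes per chromosome was set against the others by a two-sided Fisher exact test.

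Named genes were chosen by a rule: adjusted p under 0.05, exactly 1 symbol, and no overlap between the 4 arrays of one strain and the 4 of the other. For F344 minus LEW these were the 10 largest rises, the 10 largest falls and the 12 largest changes on chromosome 4; for COP minus DA the 5 largest rises and falls and the 3 largest on chromosome 4; for each other contrast the 3 largest rises and falls. For each strain the 5 genes with the largest of the smallest differences from the other strains were named, and for each list up to 4 members with the largest changes. Symbols that only number a locus were skipped, 1 among the falls and 1 on chromosome 4 for F344 minus LEW and 1 among the falls for F344 minus DA.

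The fit was tested on simulated data for F344 minus LEW, in 10 simulations of 18625 probe sets with 200 changed. It recovered 56.8% of log2 changes of 0.5, 89.6% of changes of 1 and 99.9% of changes of 2, and 5.50% of its calls were false. The simulated noise was independent between probe sets and had the same SD in all strains, and few probe sets were changed. The real arrays differ in this, so these rates need not hold for them. With lists given a strong shared factor, camera with an estimated correlation called 5.18% of unchanged lists at an unadjusted p under 0.05, and with the preset correlation 53.0%.

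Alternatives tried were quantile normalization, median centring of each array, a pseudocount at the 10th percentile of all values (19.3), no filter, a filter at the 60th percentile, a fit without intensity trend, robust moderation, array weights, the replicate number as a block, an adjusted p under 0.10, fits of the 8 arrays of 2 strains alone, the mean of a gene's probe sets, adjustment over chromosome 4 alone, and leaving out each array in turn. Array weights estimated per strain were added after seeing the data. Figures were drawn with matplotlib 3.10.9.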

Results

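Messenger RNA from the proximal femur, the end of the thigh bone that carries the hip joint and the femoral neck, was measured on 16 arrays from 4-week-old rats of 4 inbred strains: F344 (Fischer 344), LEW (Lewis), COP (Copenhagen 2331) and DA (Dark Agouti), with 4 arrays per strain. F344 and LEW are the parents of the F2 cross in which a locus for skeletal traits had been placed on chromosome 4, and the question was which genes of that chromosome differ in bone between these strains. The 31099 values per array were expression signals, scaled within each array to a 2% trimmed mean of about 1000 and with medians between 303 and 325. For arrays, the number of arrays limits the precision. The labels do not say that the replicates were separate animals, so the p-values measure the spread between these samples. All strain differences below are log2 differences of the first strain minus the second, so a positive value is a higher signal in the first strain.

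Strain was the main structure of the data. Each of the 16 arrays correlated most closely with another array of its own strain, with r across kept probe sets of 0.977 to 0.989 within strains and 0.962 to 0.973 between strains (genes are not independent replicates). The first 3 principal components carried 22.8%, 18.2% and 16.7% of the variance. The moderated F-test of limma called 5810 of 18625 kept probe sets different among the 4 strains at an adjusted p under 0.05, or 31.2%, representing 3474 of 10548 genes. The ratio of signals for the 3' end of Gapdh to those for its 5' end was 1.04 ± 0.0226 in F344, 1.02 ± 0.0235 in LEW, 1.01 ± 0.0278 in COP and 1.02 ± 0.0126 in DA (SD, n = 4). The same ratio for actin was 2.14 ± 0.128 in F344, 2.04 ± 0.151 in LEW, 1.98 ± 0.0665 in COP and 1.996 ± 0.120 in DA (SD, n = 4), and that for hexokinase had means of 3.11, 3.11, 2.88 and 3.47. The smallest exact permutation p for a Gapdh or actin ratio between 2 strains was 0.0571, unadjusted and two-sided, for actin in F344 and COP; 4 arrays against 4 allow 0.0286 at the least, which for a single separated pair adjusts to 0.514 over the 18 tests, so equal RNA quality is not shown by it. Arrays of F344 were closer to each other than those of the other strains, with a median SD of log2 signals of 0.121 against 0.154 in LEW, 0.136 in COP and 0.150 in DA. Sex was not given in the labels; of the sex-linked list, Xist, transcribed from the inactive X chromosome, had signals of 1773 to 16885 over its probe sets and the 16 arrays, the Y-linked Eif2s3y 0.432 to 25.8, Sry 13.6 to 128 and Tspy1 at most 53.3, and the Y-linked Uty 2182 to 2830.4 for one probe set and 10.1 to 102 for the other.

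**Figure D1:**
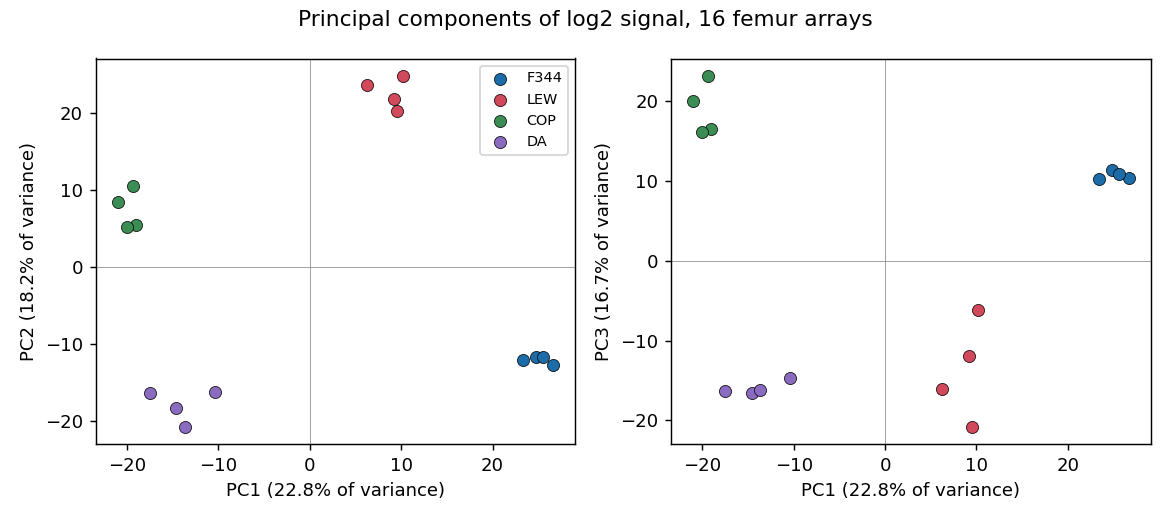
Principal components 1 and 2 (left) and 1 and 3 (right) of log2 signals of kept probe sets, with the percent of variance on each axis; each point is 1 of 16 arrays, coloured by strain. The 4 arrays of each strain lie together, along components that carry 22.8%, 18.2% and 16.7% of the variance.

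Between F344 and LEW, Ccn1 and RT1-T24-4 had the largest rises in F344. Ccn1, a secreted matrix protein that binds integrins, had signals of 1305 ± 61.6 in F344 and 123 ± 45.6 in LEW (SD, n = 4), a log2 difference of 3.49 (SE 0.22, limma adjusted p = 3.21e-10). RT1-T24-4, a class I gene of the rat histocompatibility complex, was 10.3-fold higher, with signals of 2679 ± 127 in F344 and 269 ± 79.7 in LEW (SD, n = 4), a log2 difference of 3.37 (SE 0.16, limma adjusted p = 4.02e-12). Itgal, the alpha chain of a leukocyte integrin, and Itga1, the alpha chain of a collagen-binding integrin, were higher by log2 differences of 2.97 and 2.74. The others of the 10 largest rises were RT1-CE16 (2.89), Plekhb1 (2.71), Siglec5 (2.62), RT1-A (2.61), Fcrl2 (2.18) and Gfap (2.06), where Siglec5 encodes a sialic acid-binding lectin of myeloid cells and Gfap an intermediate filament protein best known from astrocytes. The arrays of the 2 strains did not overlap for any of these genes.

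The largest falls in F344 against LEW were in Cyp4v3 and Lcn2. Cyp4v3, a cytochrome P450 of fatty acid metabolism, had signals of 104 ± 28.8 in F344 and 1676 ± 265 in LEW (SD, n = 4), a log2 difference of -4.04 (SE 0.16, limma adjusted p = 1.38e-13). Lcn2, a siderophore-binding protein of neutrophil granules, had signals of 834 ± 30.3 in F344 and 12526 ± 651 in LEW (SD, n = 4), a log2 difference of -3.91 (SE 0.066, limma adjusted p = 8.34e-20), a 15.0-fold difference. Vof16 (-3.62), the histone methyltransferase gene Setd1b (-3.47), the N6-methyladenosine reader Ythdf2 (-3.14) and Slc3a1 (-2.78), a subunit of a cystine transporter, were also lower in F344. Vpreb3, expressed in precursors of B cells, had a difference of -2.41, RT1-CE5 of -2.32 and Abca1, which exports cholesterol, of -2.29. Klhl42, a chromosome 4 gene described below, completes the 10. Of the 32 entries named for this comparison, 8 had the lower strain mean under the filter level of 174, where the fold depends on a signal close to background. RT1 genes form a family of close copies, so that probe sets can be shared between them, and other kept probe sets of Ythdf2 (-0.53) and Abca1 (median 0.56, 1 called the same way and 1 the opposite way) changed by less or otherwise.

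In all, 2567 of 18625 probe sets differed between F344 and LEW by limma at an adjusted p under 0.05, 1216 higher and 1351 lower in F344 (1009 and 1478 under median centring), with 285 changed 2-fold or more. These stand for 1529 genes, of which 734 were higher and 795 lower. Of all kept probe sets 18.3% had no overlap between the 4 arrays of one strain and the 4 of the other, where chance gives a share of 2.86%; 2217 of the called probe sets were among these. The median absolute log2 difference of called probe sets was 0.44 against a median standard error of 0.11.

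On chromosome 4, to which the locus was mapped, 104 of 606 genes differed between F344 and LEW, 51 higher and 53 lower in F344 (38 and 56 under median centring). Klhl42, a kelch-like substrate adaptor of a ubiquitin ligase, had signals of 313 ± 57.1 in F344 and 1582 ± 134 in LEW (SD, n = 4), a log2 difference of -2.35 (SE 0.13, limma adjusted p = 2.99e-11). Among genes higher in F344 were Akr1b8, an aldo-keto reductase, with signals of 1066 ± 50.9 in F344 and 436 ± 80.3 in LEW (SD, n = 4), a log2 difference of 1.31 (SE 0.15, limma adjusted p = 1.48e-06), Inmt (1.25), an indolethylamine methyltransferase, Actr3b (1.08), an actin-related protein, Usp18 (0.93), a protease that removes the interferon-induced modifier Isg15, Antxr1 (0.80), Gimap4 (0.78), a GTPase of lymphocytes, and A2m (0.72), a plasma protease inhibitor. Lower in F344 were Nom1 (-1.09), Osbpl3 (-1.03), an oxysterol-binding protein, Zfp956 (-0.88) and the chaperone gene Dnajb6 (-0.78). Only 6 of the called genes changed 2-fold or more. The call of Zfp956 rested on single arrays: its limma adjusted p was 0.0671 without F344 replicate 3 (log2 difference -0.69) and 0.0641 without LEW replicate 3 (-0.77), in a range of 0.0101 to 0.0671 over its alternatives. Klhl42 had 1 other kept probe set, which was not called (-0.37), as was that of Osbpl3 (0.059), while that of Nom1 was called the same way (-0.44).

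**Figure D2:**
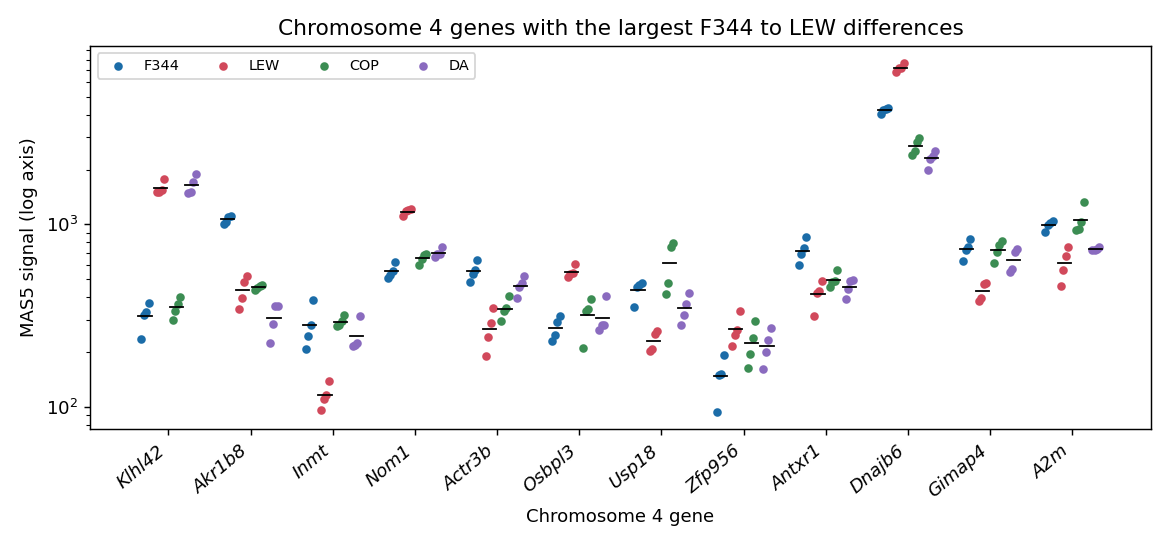
MAS5 signal on a log axis for the 12 chromosome 4 genes with the largest F344 to LEW differences; each point is 1 array, coloured by strain, and each bar is the mean of 4 arrays. Klhl42 has mean signals of 313 in F344, 1582 in LEW, 351 in COP and 1648 in DA.

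The share of genes that differed between F344 and LEW was 17.2% on chromosome 4 against 14.3% on the other chromosomes, an odds ratio of 1.24 with a 95% confidence interval of 0.985 to 1.54 (two-sided Fisher exact test p = 0.0573, adjusted over 21 chromosomes 0.318), so the excess did not pass the threshold. Adjusted over the chromosome 4 genes alone, 112 of 606 passed. Chromosome 17 passed, with 61 of 289 genes, or 21.1% (Fisher exact adjusted p = 0.0457). Dividing chromosome 4 into 6 blocks of 101 neighbouring genes, the calls numbered 15, 23, 23, 5, 21 and 17 from Dnajb6 to Resf1. The block from Aup1 to Crbn held 5, which differed from the rest of the chromosome (two-sided Fisher exact p = 1.34e-04, not adjusted over the 6 blocks). The interval of the locus was not stated in the labels, so the whole chromosome was tested. The Fisher tests treat genes as independent, but neighbouring genes shared their division of the strains in 29.1% of pairs against 17.9% at random, so the p-values of chromosomes and blocks can be too small.

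**Figure D3:**
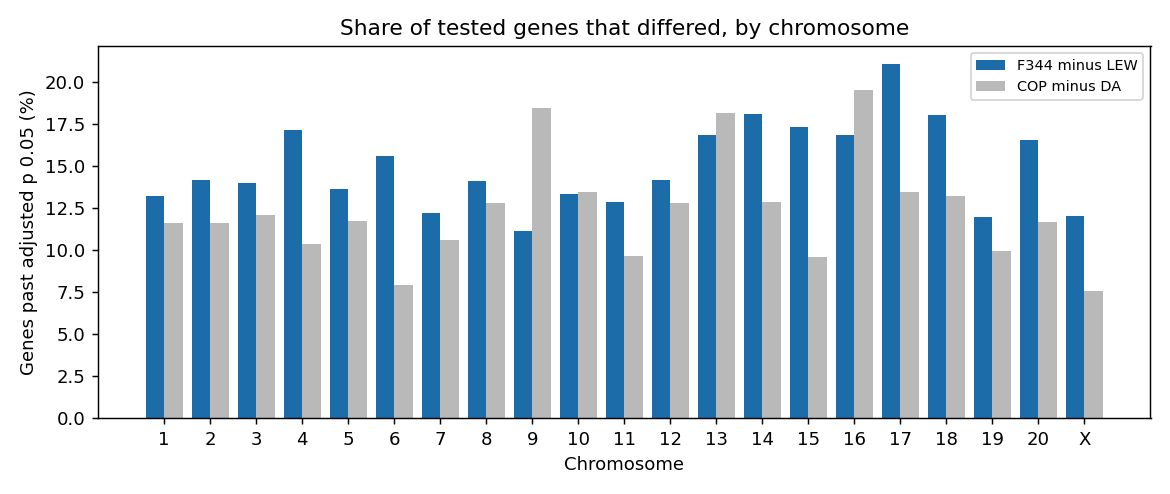
Percent of tested genes past an adjusted p of 0.05 on each chromosome, for F344 minus LEW (blue) and COP minus DA (grey). Chromosome 4 held 17.2% in the first comparison and 10.4% in the second; chromosome 17 held 21.1% in the first.

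Of the lists of genes fixed beforehand, those of B lymphoid, cell cycle, erythroid, megakaryocyte and neutrophil granule genes had more members called lower than higher in F344 against LEW. Of all kept probe sets 13.8% were called, and of all genes 1529 of 10548, so counts near that share do not set a list apart. For B lymphoid markers, 10 of 13 kept members fell and 0 rose, led by Vpreb3 (-2.41), Fcrla (-0.82), Cd79b (-0.80) and Pou2af1 (-0.79). For the cell cycle, 18 of 35 fell and 0 rose, with Aurkb (-0.86), Tyms (-0.86) and Ttk (-0.69). For erythroid genes, 13 of 23 fell and 1 rose, with Hba-a3 (-1.80), Hemgn (-0.51) and Car1 (-0.48), while Sptb (0.50) rose. For megakaryocyte genes, 4 of 13 fell and 0 rose, with Pf4 (-1.59) and Tubb1 (-0.63), and of neutrophil granule genes 4 of 19 fell, with Camp (-0.44) and Itgam (-0.54) beside Lcn2, and 1 rose. The adjusted p-values of camera with an estimated correlation were 0.0955 for B lymphoid, 0.194 for cell cycle, 0.206 for erythroid, 0.373 for megakaryocyte and 0.309 for neutrophil granule lists, so no list passed. Adjusted over the list alone, 11 B lymphoid, 24 cell cycle, 18 erythroid, 6 megakaryocyte and 5 neutrophil granule members passed. The LEW arrays were uneven. For each of these lists, the means of all F344 arrays still lay below those of all LEW arrays. The exact permutation p was 0.0286 for each, unadjusted and the smallest possible, and 0.0857 adjusted. The megakaryocyte list mean, centred on all 16 arrays, was -0.20 on LEW replicate 4, 0.099 to 0.30 on the other LEW arrays and -0.29 to -0.25 in F344. LEW replicate 4 also had the lowest LEW means of the erythroid (0.0055), cell cycle (-0.057) and neutrophil (-0.10) lists. It had the highest of the cartilage (0.39), osteocyte (0.33) and osteoblast (0.20) lists. LEW replicate 1 lay at the other end for the erythroid (0.29), neutrophil (0.11) and cartilage (-0.38) lists.

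The lists of interferon response, monocytes and macrophages, antigen presentation, and T and natural killer cells had more members called higher than lower in F344. Of interferon-response genes, 12 of 27 kept members rose in F344 and 0 fell, with Isg15 (1.02), Irf7 (0.92) and Ifi27 (0.85). Of monocyte and macrophage markers, 11 of 19 rose and 0 fell, with Fcgr3a (0.99), Mertk (0.61) and C1qb (0.41). In antigen presentation, 6 of 18 rose and 1, RT1-CE5, fell; the class II genes RT1-Ba, RT1-Da and RT1-Bb rose by 1.25, 0.92 and 0.89. Of T and natural killer cell genes, 2 of 7 rose, Il2rb (1.07) and Cd3g (1.04). With an estimated correlation the adjusted p of camera was 0.309 for interferon response, 0.0955 for monocyte and macrophage, 0.0955 for antigen presentation and 0.544 for T and natural killer cells. Adjusted over the list alone, 14 interferon, 15 macrophage (12 higher and 3 lower), 8 antigen presentation and 2 T and natural killer cell members passed. The list means of each of these separated the arrays of F344 and LEW (exact permutation p = 0.0286, unadjusted, and 0.0857 adjusted). The preset correlation of camera called 15 of 28 lists, of which 0 held with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way, called 12.

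Few genes of bone cells and cartilage passed between F344 and LEW, where 1529 of all 10548 tested genes passed. Of osteoblast and bone matrix genes 1 of 21 rose, Phospho1 (0.27), a phosphatase of mineralization, and 0 fell; of osteocyte genes 1 of 9 rose, Ankh (0.32), a pyrophosphate transporter. Of osteoclast genes 1 of 15 rose, where median centring gave 0 rises and 1 fall and quantile normalization 1 of each. Of growth plate cartilage genes 0 of 21 passed limma's adjusted threshold, and 0 of 21 adjusted over the list alone. The largest cartilage differences were those of Matn1 (0.78, limma adjusted p = 0.145) and Ihh (0.55, limma adjusted p = 0.154). The median cartilage difference was 0.23, but the list mean ran from -0.38 to 0.39 over the LEW arrays, against 0.14 to 0.20 in F344. With that spread, the lack of calls does not show that cartilage genes were equal. In the insulin-like growth factor axis 4 of 19 rose and 3 fell: Igf1 (-0.80), the growth factor itself, Igf2bp3 (-0.66) and Igfbp4 (-0.55) fell, and Socs2 (1.05), a negative regulator of growth hormone signalling, rose. In the bone morphogenetic protein and transforming growth factor beta pathway 4 rose and 1 of 42 fell, with Tgfbr3 (1.76) and Bmp3 (-1.14); in the Wnt pathway Tcf7 (0.63) rose and Lef1 (-0.60) fell, out of 31. Of immediate early and heat shock genes 5 of 21 rose, including Fos (0.92) and Ier3 (0.83). Skeletal muscle genes rose in 4 of 35 cases, with Myh4 (0.67), all 35 members had differences above 0, and 1 rise passed under median centring. The muscle list mean ran from -0.27 to 0.25 over the LEW arrays and from 0.11 to 0.19 in F344. The arrays of the 2 strains thus overlapped (exact permutation p = 0.143, unadjusted). The adjusted p of camera with an estimated correlation was 0.822 for osteoblast, 0.656 for cartilage, 0.656 for the insulin-like growth factor axis and 0.656 for muscle lists. Adjusted over the list alone, 0 osteoblast, 0 osteoclast, 1 osteocyte, 9 growth factor axis, 5 bone morphogenetic protein, 2 Wnt, 10 immediate early and 1 muscle members passed.

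The other lists, given as rose and fell out of kept members, were as follows. They compare with 734 rises and 795 falls in all 10548 genes tested. For adipocyte genes, 3 rose and 0 fell of 20. For endothelial genes, 4 rose and 3 fell of 19. For the fibroblast and vascular growth factor axis, 4 rose (2 under median centring) and 0 fell of 23. For glutathione and xenobiotic genes, 2 rose and 3 fell of 26. For lysyl and collagen processing, 1 rose and 1 fell of 24. For mast cell, basophil and eosinophil genes, 2 rose and 1 fell of 15. Oxidative phosphorylation genes rose in 5 of 49 cases with 0 falls (3 under median centring, 8 under quantile normalization), and ribosomal protein genes fell in 1 of 27 (2 under quantile normalization). Matrix proteases and their inhibitors had 2 rises, among them Timp1 (0.45), and 1 fall in 24, and the RANKL, TNF and cytokine list had 4 rises and 1 fall in 22, led by Tnfsf10 (1.19) and Ccl5 (1.06). Over all 28 lists, camera with an estimated correlation called 0 at an adjusted p under 0.05, with 5 lists at an unadjusted p under 0.05.

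**Figure D4:**
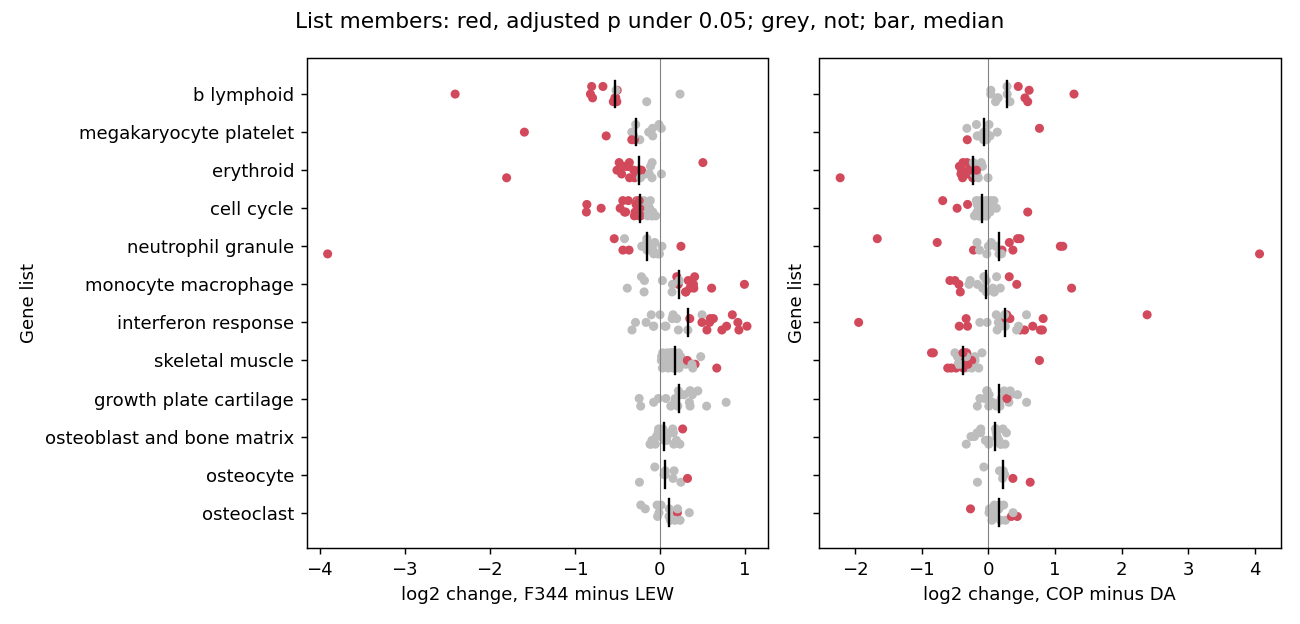
log2 change of each kept member of 12 gene lists, for F344 minus LEW (left) and COP minus DA (right); red points passed an adjusted p of 0.05, grey points did not, and the bar is the list median. The median of B lymphoid genes was -0.53 on the left and 0.28 on the right; no list passed camera with an estimated correlation.

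COP and DA, which share no arrays with F344 and LEW, differed most in Myo5c, an unconventional myosin, with mean signals of 7437 in COP and 64.8 in DA (n = 4), a log2 difference of 6.86 (SE 0.12, limma adjusted p = 5.37e-20); its other probe set gave 5.19. Atp6ap1l (5.29), Lcn2 (4.06), Abca1 (2.57) and the interferon-induced GTPase gene Mx2 (2.38) were also higher in COP, with Lcn2 at 17160.4 in COP and 1023 in DA. Lower in COP were the defensin gene Defa7 (-2.96), Klhl42 (-2.23), the alpha globin gene Hba-a3 (-2.22), Anks1b (-2.19) and Prss35 (-2.18). On chromosome 4, Klhl42 was followed by Cped1 (1.16) and Cyren (-1.10). In total 2211 probe sets differed by limma, 1106 higher and 1105 lower in COP, standing for 1282 genes. Of the 13 entries named, 4 had the lower mean under the filter level of 174; the DA mean of Atp6ap1l was 23.2, so that its size is uncertain (4.42 with the pseudocount of 19.3). The other kept probe set of Klhl42 (0.18) was not called, and of the 3 others of Abca1 (median -0.040) 1 was called in the same direction.

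Between COP and DA no list passed camera with an estimated correlation, and the counts below are of single genes. Of all kept probe sets 11.9% were called, and of all genes 1282 of 10548, so counts near that share do not set a list apart. Of skeletal muscle genes 19 of 35 fell and 1 rose, with Myh3 (-0.85), Pygm (-0.82) and Myh4 (-0.61) lower and Myh1 (0.77) higher. Quantile normalization left 11 falls. The muscle list mean was uneven over the COP arrays, from -0.50 to -0.053, against 0.0066 to 0.28 in DA. The arrays of COP and DA did not overlap in it (exact permutation p = 0.0286, unadjusted, and 0.0857 adjusted). Of adipocyte genes 11 of 20 fell, led by Scd (-2.08), a desaturase of fatty acids, Thrsp (-1.30) and Cidea (-1.14). Of erythroid genes 14 of 23 fell, and of neutrophil granule genes 8 rose and 3 fell, with Fcnb (1.12) and Padi4 (-1.66). In interferon response 10 rose and 4 fell, with Mx1 (0.82) higher and Ifit1 (-1.94) lower in COP, while the interferon list mean was 0.47 and 0.52 on COP replicates 2 and 4 but 0.12 and 0.19 on COP replicates 1 and 3, against -0.046 to 0.16 in DA. Antigen presentation fell in 5 of 18 cases, including RT1-Db1 (-1.08). Of B lymphoid genes 5 of 13 rose. With an estimated correlation the adjusted p of camera was 0.472 for muscle, 0.197 for adipocytes, 0.197 for erythroid cells and 0.510 for neutrophil granules, and 0 of 28 lists passed, with 4 at an unadjusted p under 0.05; the preset correlation called 13 and fry 9.

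In the other lists between COP and DA, T and natural killer cell genes rose in 3 of 7 cases, with Nkg7 (0.59) and Lck (0.51), and oxidative phosphorylation genes fell in 9 of 49, with Ndufv2 (-0.40), and in 5 under quantile normalization. Osteocyte genes rose in 2 of 9 cases, Mepe (0.63) and Ankh (0.37), osteoclast genes rose in 2 and fell in 1 of 15, and osteoblast genes changed in 0 of 21 by limma, while median centring gave 2 osteoblast falls and quantile normalization 3 osteoblast rises and 4 osteoclast rises. In the insulin-like growth factor axis Socs2 (1.32) rose, and Igf2 (-0.74) and its imprinted neighbour H19 (-0.52) fell. In the bone morphogenetic protein list Bmp4 (1.01) and Bmpr1a (0.77) were among 5 rises, 3 under median centring. Glutathione and xenobiotic genes fell in 7 and rose in 3 of 26, with Gclc (-0.91). Monocyte and macrophage genes rose in 3 and fell in 4 of 19, and cell cycle genes rose in 1 and fell in 3 of 35. Adjusted over the list alone, 32 muscle, 14 adipocyte, 17 erythroid, 13 neutrophil granule, 17 interferon and 5 B lymphoid members passed. With an estimated correlation the adjusted p of camera was 0.197 for T and natural killer cells, 0.197 for antigen presentation, 0.352 for B lymphoid genes and 0.510 for interferon response.

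Klhl42 was among the 25 chromosome 4 genes called in both F344 minus LEW and COP minus DA; the other 79 of the 104 genes did not pass in the second comparison. Of the 12 named chromosome 4 genes, Akr1b8 (0.60), Usp18 (0.78) and A2m (0.51) also passed in COP minus DA, all in the same direction as between F344 and LEW. Across the genome 376 genes were called in both comparisons, and 197 of these, or 52.4%, had the same sign; both comparisons use the same standard error per gene, so that the number for unrelated lists is not known. On chromosome 4, 63 of 606 genes differed between COP and DA, or 10.4%, against 12.3% elsewhere (Fisher exact adjusted p = 0.478). Chromosomes 9 (18.4%, adjusted p = 0.00235), 13 (18.2%, 0.0143) and 16 (19.5%, 0.00235) held larger shares between COP and DA by the exact test, and chromosomes 6 (7.93%, 0.0215) and X (7.59%, 0.0462) smaller ones.

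Against COP, F344 had higher Clec3b (5.24), the gene of tetranectin, Ucp1 (3.45), the uncoupling protein of brown fat, and Prcp (2.68), and lower Lcn2 (-4.36), Setd1b (-4.30) and Mx2 (-4.19), among 3699 probe sets called by limma, 1750 higher and 1949 lower in F344. The COP means of Clec3b (34.5 ± 28.6) and Ucp1 (149 ± 86.1; SD, n = 4) and the F344 mean of Mx2 (67.3) were under the filter level, so their sizes and order are uncertain, with Clec3b at 4.40, Ucp1 at 3.25 and Mx2 at -3.82 under the pseudocount. Against DA, F344 had higher Myo5c (6.43), Atp6ap1l (4.68) and Clec3b (4.61) and lower Cyp4v3 (-3.99), Setd1b (-3.58) and Prss35 (-3.23), among 2998 called, 1426 higher and 1572 lower. LEW had higher Clec3b (5.07), Ythdf2 (2.94) and Cemip2 (2.54) than COP and lower Mx2 (-4.09), RT1-T24-4 (-3.49) and Ccn1 (-3.44); of 2559 called probe sets 1164 were higher and 1395 lower, while median centring of each array gave 1377 higher and 1087 lower. The balance also turned under median centring for F344 minus COP (1816 higher and 1720 lower) and LEW minus DA (1011 and 891; 983 and 965 with quantile normalization), and for COP minus DA centring gave 919 higher and 1170 lower, so no balance of directions is read from these counts. Against DA, LEW had higher Myo5c (7.41), Atp6ap1l (5.17) and Clec3b (4.44) and lower Itgal (-3.70), Ccn1 (-3.56) and RT1-T24-4 (-3.51), among 1946 called, 936 higher and 1010 lower. The lower means were under the filter level here too for all of these genes but RT1-T24-4. This also held for Myo5c, Atp6ap1l, Clec3b and Cyp4v3 in F344 minus DA, and for Clec3b, Cemip2, Mx2 and Ccn1 in LEW minus COP. Their sizes and order are likewise uncertain: under the pseudocount F344 minus DA gave 3.82 for Atp6ap1l and 4.02 for Clec3b. LEW minus DA gave 4.30 and 3.85. Interferon-response genes were lower in LEW than in COP in 16 of 27 cases and lower than in DA in 9 of 27, with 0 higher in either, while camera with an estimated correlation gave adjusted p-values of 0.215 and 0.518. Against COP, F344 had lower B lymphoid genes in 12 of 13 cases and higher skeletal muscle genes in 23 of 35, with adjusted p-values of camera of 0.0988 and 0.551 with an estimated correlation, and against DA lower cell cycle genes in 21 of 35, with 0.266. In these 4 comparisons camera with an estimated correlation called 0 of 28 lists each, with 3, 5, 4 and 1 at an unadjusted p under 0.05, where the preset correlation called 9, 12, 8 and 8 and fry 15, 8, 7 and 4, for F344 minus COP, F344 minus DA, LEW minus COP and LEW minus DA.

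Some genes set one strain apart from each of the others in the same direction. F344 had 442 such genes, 164 higher and 278 lower, led by Cyp4v3, with mean signals of 104 in F344 against 1236 to 1676 in the others, then Setd1b (3.47), Slc3a1 (2.59), Itga1 (2.56) and Vof16 (2.26), given with the smallest absolute log2 difference from another strain. LEW had 222, led by Ccn1 (3.44), RT1-T24-4 (3.37), Itgal (2.97), Ythdf2 (2.94) and RT1-CE16 (2.48); Ythdf2 was higher in LEW, the others lower. COP had 356, led by Mx2 (2.38), Anks1b (1.84), Haghl (1.57), Ube2d1 (1.45) and Zfp597 (1.36), of which Mx2 and Zfp597 were higher. DA had 176, led by Myo5c (6.43), Atp6ap1l (4.68), Defa7 (2.44), Prss35 (2.18) and Ifit1 (1.94); the mean signal of Myo5c was 64.8 in DA against 5486 to 10851 elsewhere. The 3 contrasts of a strain share its 4 arrays, so the 3 calls of a gene are not independent.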

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

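The tests of arrays apart from the others of their strain were set by a fixed rule; by chance Dixon's ratio picks out about 1 in 20 groups. Of 144 groups of 4 arrays for named genes 9 had an array apart from the rest (7.2 by chance), of 112 groups for list means 6 (5.6 by chance), and of 16 groups for array quality 1 (0.8 by chance). F344 replicate 1 and COP replicate 1 accounted for 4 each, LEW replicate 4 for 2.

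For Abca1 the signal of COP replicate 1 was 3770.5, above the 2929 to 2981 of the other COP arrays. For Atp6ap1l COP replicate 1 was at 755, below 917 to 949. Defa7 was at 464 on F344 replicate 1, against 349.8 to 357. Haghl was at 31.4 on COP replicate 3, against 97.6 to 106, and at 129 on DA replicate 3, against 257 to 285. Klhl42 was at 1781 on LEW replicate 2, against 1502 to 1539. Setd1b was at 2544 on DA replicate 1, against 1863 to 1963. Usp18 was at 355 on F344 replicate 1, against 455 to 479. Ythdf2 was at 7506 on LEW replicate 4, against 6449 to 6488.

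List means are averages of members' log2 signals, each centred on its mean over all 16 arrays. The B lymphoid mean was -0.40 on F344 replicate 3, against -0.53 to -0.52 on the other F344 arrays, and 0.084 on LEW replicate 1, against 0.19 to 0.20. The megakaryocyte and platelet mean was -0.29 on F344 replicate 1, against -0.25 on the others, and -0.12 on COP replicate 1, against 0.12 to 0.16. The osteoblast and bone matrix mean was 0.20 on LEW replicate 4, against -0.062 to -0.056. The skeletal muscle mean was 0.11 on F344 replicate 1, against 0.18 to 0.19. The mean correlation of COP replicate 1 with the other COP arrays was 0.984014, against 0.985285 to 0.985492.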

How the results depend on the processing

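Array weights per strain were chosen after seeing the data, all other settings before. Counts of called probe sets stayed within 1.5 times the reported count in every comparison and setting. Without 1 replicate they ranged from 4934 to 6176 among the 4 strains (5810 with all), 1907 to 2786 for F344 minus LEW, 1524 to 2462 for COP minus DA, 2891 to 3892 for F344 minus COP, 2263 to 3278 for F344 minus DA, 2153 to 2715 for LEW minus COP, 1542 to 1975 for LEW minus DA and 74 to 120 for chromosome 4 genes. The other settings gave 2177 to 3534 for F344 minus LEW (2718 with weights per strain) and 85 to 138 for chromosome 4. For LEW minus DA they gave 1411, with only the 8 arrays of the 2 strains, to 2678, at an adjusted p under 0.10. Lists were the exception: 0 were called for F344 minus LEW, without any 1 replicate also 0, but 1 with the stricter filter, 3 at an adjusted p under 0.10, 15 with the preset correlation of camera and 12 with fry; the cause was not tested.

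Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated with a mean r of -0.0046 over 24 pairs, 0 above 0.1, and 4 of 16 arrays correlated best with their own number. With the replicate block the counts were 5462 among strains, 2424 for F344 minus LEW, 2087 for COP minus DA, 3518 for F344 minus COP, 2878 for F344 minus DA, 2457 for LEW minus COP, 1859 for LEW minus DA, 96 for chromosome 4 and 0 lists. Of 1781 values of 67 named gene differences, 1779 kept their direction and side of the threshold, 2, both of Zfp956, lost the call, and 0 turned. The named genes were chosen from these same arrays for large differences without overlap, so most could hardly lose their call here. Of 6278 values of all called genes followed, 148 lost the call and 0 turned; of 1945 values of uncalled list members 131 gained one. Detection calls, which would show signal over background, were not used here, and changes with a mean under 174 rest on the dimmest signals.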

Other observations

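The tests of the marrow and muscle explanations were chosen only after their results were seen; those of probe variants, neighbouring genes and splits of the arrays were written before.

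Several genes divided the 4 strains into pairs. F344 and LEW stood apart from COP and DA for Clec3b, with mean signals of 1015 and 905 against 34.5 and 50.2, for Ephx2, a soluble epoxide hydrolase (733 and 669 against 139 and 158), and, in the other direction, for the splicing factor gene Srsf3 (211 and 209 against 906 and 1143). F344 and COP stood apart from LEW and DA for Klhl42, for Hba-a3, for Drg1 (230 and 207 against 699 and 762), and, being higher, for Uhrf1, a chromatin protein of dividing cells (2017 and 2489 against 764 and 705). F344 and DA stood apart from LEW and COP for Abca1 (575 and 532 against 2821 and 3157), Rnf6 (457 and 396 against 160 and 143) and G0s2, an inhibitor of lipolysis (3476 and 3725 against 1866 and 1472). Of the 3474 genes that differed among strains, 143, 90 and 65 fell into these divisions, and 1118, or 32.2%, into 1 of the 7 divisions that set 1 strain or a pair apart; these leading genes were chosen after their values were seen.

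A hypothesis is that such differences were inherited in chromosome segments. Neighbouring genes with a division shared it in 29.1% of 1094 pairs, against a mean of 17.9% and at most 22.2% in 10000 random reassignments of divisions to genes (permutation p = 1e-04, the smallest they can give). Pairs whose symbols differed in the first 3 letters gave 29.0% of 1074 pairs, so families of like-named genes were not the whole source. This goes with inheritance in segments, while shared regulation of neighbours stays open and was not tested. Strain variants under the probes, taken up next, could be shared by neighbours in the same way. The result therefore does not show that the shared differences are ones of expression.

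Changes of 2-fold or more between F344 and LEW could in part come from a strain variant under the probes of 1 probe set. For the 21 of 114 such genes that had other kept probe sets, the median ratio of the others' log2 change to that of the representative was 0.0349 (quartiles -0.155 to 0.408), and 14 lay under 0.25; among genes changed under 2-fold it was 0.572. In the other 5 contrasts the ratio for changes of 2-fold or more was higher, 0.261 to 0.750, and in F344 minus DA (0.750) it exceeded that of smaller changes (0.537). Ythdf2 had another probe set changed the same way (-0.53 against -3.14), and that of Klhl42, at -0.37 against -2.35, was not called. A difference between transcript ends stays open, and genes with 1 kept probe set were outside the test.

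Of 13 B lymphoid genes 10 were called lower in F344 than in LEW, although the list did not pass camera (adjusted p = 0.0955 with an estimated correlation), and a smaller share of marrow in the F344 bone is a candidate explanation. In its simplest form the marrow lineages would move alike. The B lymphoid mean less the neutrophil mean differed between the strains by -0.303 (log2), or -2.97 SD of the arrays. The exact permutation p was 0.0286, the smallest possible for 4 against 4. The macrophage list mean was higher in F344 (0.21). The neutrophil mean rests in part on Lcn2 (-0.35 with it, -0.16 without), and the difference was -0.50 without Lcn2 and -0.35 without Lcn2 and Vpreb3. The erythroid (-0.30) and megakaryocyte (-0.33) means were lower in F344 too, which goes with a smaller marrow share. These values show that the lists did not move by the same amount. The B lymphoid list had the most negative difference in mean of the lists tested (-0.66), and its comparison was chosen after that was seen. It therefore cannot decide whether marrow share is the whole cause. Marrow share, as the whole or a part, and a difference in lineages between strains stay open.

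Of 35 skeletal muscle genes 19 were called lower in COP than in DA, 11 under quantile normalization, and the list did not pass camera (adjusted p = 0.472 with an estimated correlation); more muscle left on the DA pieces could give such falls. Of 35 members 34 lay below 0, and the correlation between members over arrays was 0.598, so they moved together from array to array; this is consistent with a difference in attached muscle. Muscle genes of the bone itself cannot be excluded by this, and a strain difference in muscle stays open. The SD of the muscle list mean was 0.041 in F344, 0.22 in LEW, 0.21 in COP and 0.12 in DA.

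No other split tried gave as many called probe sets or chromosome 4 genes as the real strains. The other splits mix arrays of different strains, so strain differences widen the spread within their groups and lower their counts. Chance in the choice of samples, or a sample or processing difference that follows strain, is therefore not excluded by the splits. Of the 35 splits of the 8 arrays of 2 strains only 1, the real one, gave as many as 2567 for F344 minus LEW (highest other 1), 2211 for COP minus DA (3), 3699 for F344 minus COP (1), 2998 for F344 minus DA (20), 2559 for LEW minus COP (38), 1946 for LEW minus DA (5) and 104 chromosome 4 genes (0). Of 100 splits of the 16 arrays 1 gave 5810 or more (highest other 3). For lists, where the real count was 0, all 35 splits gave as many (highest other 0), so nothing is excluded.

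The arrays of F344 agreed more closely than those of the other strains: the median SD of log2 signals was 0.12 in F344, 0.15 in LEW, 0.14 in COP and 0.15 in DA. Among the brightest of 5 equal groups of probe sets it was 0.063, 0.10, 0.082 and 0.098, and among the dimmest 0.24, 0.26, 0.24 and 0.27. The SD of the neutrophil list mean was 0.0028, 0.089, 0.024 and 0.10, but that of T and natural killer cells was larger in F344 (0.12) than in LEW (0.048). The fit pools the spread of all strains, so close F344 arrays can make p-values too small in comparisons without F344. Fitted on their own arrays alone, LEW minus DA had 1411 calls against 1946. The drop was smaller in the other comparisons without F344. Such a fit gave at least 1852 calls against 2211 for COP minus DA, and at least 2081 against 2559 for LEW minus COP. A fit of 8 arrays also has fewer residual degrees of freedom, so the share due to F344 is not known. Whether the F344 arrays were repeats or pools was not tested.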
